A study of Mus musculus with 6 samples.

How the data were processed

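Gene expression was measured by RNA sequencing of cervical spinal cord from 3 imiquimod-treated and 3 vehicle-treated mice, 1 library per mouse. The 2 groups were compared once, with all 6 libraries. Per the labels' protocols, tissue was flash frozen, RNA was extracted with TRIzol and libraries were sequenced on an Illumina instrument. The deposited files give 1 FPKM value (fragments per kilobase of exon, scaled by library size) per gene and library for 54532 Ensembl genes. HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1, with the mm10 build, are named in the submitters' processing notes, which give no roles or order. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Gene symbols came from a names table, which held 54409 of the identifiers. Coordinates, exon lengths and GC content came from GENCODE release M21 on the same assembly, which held 54495 of them.

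FPKM multiplied by exon length fell on whole multiples of 1 step per library. Of the values under 1000 fragments, 97.4% to 97.6% per library came out whole within 0.05 fragments, so fragments per gene could be recovered. The totals implied by the steps were proportional to median-of-ratios size factors of the recovered fragments, with a spread of 0.0265% between libraries. The deposited FPKM therefore appear to have been scaled by such factors before deposit, which is an inference from the values. No further scaling was applied for the main test. The recovered totals ran from 18174420 to 23200999 fragments. A gene of 2 kb with 3 fragments, the floor used here, has an FPKM of 0.0639 to 0.0863. Intervals of count ratios are exact 95% intervals at equal depth and cover counting error only. No pair of libraries held identical values. Gapdh was listed at 1.56 to 2.15 FPKM in 5 libraries and at 26.4 FPKM in imiquimod replicate 3. Reads shared with its pseudogenes may be missing from the values, but that alone would not set 1 library apart. Why imiquimod replicate 3 differed was not tested, and its values of multi-copy genes may not compare with the others. Genes with near-identical copies (MHC class I, Ifi, Oas and Gbp families, C4b, hemoglobins, ribosomal proteins) are uncertain for these reasons.

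The files hold FPKM, so the main test was the one written for that case before the data were examined, in place of a count test: limma 3.58.1 with a mean-variance trend on log2(FPKM + 0.1), in R 4.3.3. Genes with a mean FPKM of at least 0.5 in either group entered, so a gene near 0 in vehicle cords entered only if it was higher in imiquimod cords, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene p-values in the text are from this limma fit. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the rest. On 5 simulated sets of this comparison (16275 genes, 200 of them changed), the fit recovered 80.2% of genes changed 2-fold and 96.0% of those changed 4-fold. Of its calls 8.41% were false, above the nominal 0.05. Every simulated gene had the same dispersion (0.0056) in both groups. In the data, voom's sample quality weights were 1.63 to 1.80 for vehicle and 0.484 to 0.65 for imiquimod libraries. The simulated rates therefore need not hold for the real comparison. Library measures were compared by two-sided exact permutation tests, which cannot go below 0.1 here.

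A set of 45 gene lists was fixed before the data were examined. One, adipocytes, had 2 measured genes (1 lower, Cidea) and was not tested. The other 44 were tested with camera, with an inter-gene correlation preset to 0.01, and again with the correlation estimated and with fry. The lists were: interferon-stimulated genes, MHC class I and class II presentation, systemic inflammation and STAT3 response, Toll-like receptor and NF-kB pathway, IL-23 and IL-17 axis, cytokines and chemokines, complement, reactive astrocyte genes, activated microglia genes, glucocorticoid-responsive genes, immediate early genes, circadian clock genes, itch and pain neuropeptides and receptors, glutamate receptors and transporters, GABA and glycine signalling, cholesterol biosynthesis, cell cycle genes, heat shock and unfolded protein response, hypoxia and glycolysis, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, nuclear-encoded respiratory chain, and sex-linked genes. The markers were of neurons, cholinergic and motor neurons, sensory ganglion neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors and new oligodendrocytes, homeostatic microglia, border macrophages, endothelium, pericytes and smooth muscle, meningeal fibroblasts, Schwann cells, ependymal cells, neutrophils, monocytes, T and NK cells, B and plasma cells, red blood cells, skeletal muscle, keratinocytes and adipocytes.

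Named genes followed a rule fixed beforehand. It took the 12 genes with the smallest p in each direction, with at least 1 CPM and non-overlapping groups, and up to 4 members with the smallest p of each list past the threshold. It also took such members of 8 lists whatever their result, and Tlr7, Isg15, Irf7, Lcn2, Gfap, Aif1, Stat3, Il17ra, Grp and Grpr always. This gave 144 genes, of which 128 passed. Results of some single genes are not reported here. A further 37 genes were chosen after their values were seen, to name members behind small counts or list members of interest: Tgtp1, Slfn5, H2-DMb1, Il33, Cxcl12, Ccl12, Cxcl9, Crh, Penk, Tac1, Pnoc, Ntrk2, Ntsr2, Trem2, P2ry12, S100a8, Ogn, Adm, Hk1, Hk2, Ldha, Ndrg1, Nr1d1, Higd1b, Kcnj8, Rgs5, Thbs2, Ccdc153, Rarres2, Csf3r, Ighm, Krt10, Cidea, Mfsd2a, Sgk1, Ret and Slco1c1.

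Alternatives were library totals in place of the deposited scaling, no filter on low values (any gene with a value), a minimum FPKM of 1, at least 1 CPM in 3 libraries, pseudocounts of 0.01 and 1, limma-voom on recovered fragments without and with sample quality weights, an adjusted p under 0.1, a log2 change of at least 1, the replicate number as a block, removal of mitochondrial and hemoglobin genes, and each library left out in turn. Thinning to equal depth and removal of length and GC trends were added after the data were seen. The planned edgeR and DESeq2 fits were not run, and limma-voom was the test run on recovered fragments.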

Results

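RNA was sequenced from the cervical spinal cord of 6 C57BL/6 mice. In 3 mice a psoriasis-like dermatitis had been induced with 50 mg of 5% imiquimod cream, an agonist of Toll-like receptor 7 (Tlr7), put on the shaved nape once a day on 2 days. The other 3 mice received vehicle cream. Each library came from a separate mouse, so the spread within a group is a spread between animals. The deposited values were FPKM for 54532 genes. The fragments recovered from them ran from 18174420 to 20672895 per vehicle library and from 21242434 to 23200999 per imiquimod library. Every imiquimod library was thus deeper than every vehicle library (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

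The comparison asks what changes in the spinal cord segments that serve the neck skin when that skin carries an imiquimod-induced dermatitis. Higher in the imiquimod cords were 48 of 50 interferon-stimulated genes, all 20 of MHC class I presentation, 13 of 22 cytokines and chemokines (2 were lower), 12 of 18 complement genes and 29 of 36 activated microglia genes. The lists passed with a preset correlation between genes, and no list did with an estimated one. Isg15, an interferon-induced ubiquitin-like protein, was 18.2 ± 7.86 FPKM in vehicle and 301 ± 91.7 FPKM in imiquimod mice (SD, n = 3 each). H2-K1, a classical MHC class I heavy chain, was 53.6 ± 12.3 against 670.3 ± 51.1 FPKM. Of 51 neuropeptides and receptors of the dorsal horn 13 were higher and 2 lower, with Gal (galanin) at 6.1 ± 0.487 against 20.6 ± 2.36 FPKM. Lower were 5 of 14 astrocyte markers (1 was higher), 6 of 12 markers of oligodendrocyte precursors and new oligodendrocytes, and 5 of 13 mitochondrially encoded mRNAs. Gja1, the main gap junction protein of astrocytes, was 32.8 ± 0.789 against 15.3 ± 0.628 FPKM.

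Of 16513 genes tested with limma on log2(FPKM + 0.1), 2326 differed at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1444 were higher and 882 lower in imiquimod mice. The higher genes made up 62.1% of the calls, but 46.0% (1262 higher, 1480 lower) once each library's trend on exon length and GC content was removed, so which direction holds more genes is not settled. At a change of at least 1 on the log2 scale, 623 genes were higher and 70 lower. In all 2326 genes, every library of one group lay above every library of the other, as in 37.9% of the genes tested, where chance gives 10%. The groups separated on the first principal component, which held 50.4% of the variance. Correlations of log2 values across genes, which are not independent replicates, ran from 0.958 to 0.972 within groups and from 0.920 to 0.952 between them. Leaving out 1 library moved the 2326 calls to 847 (660 higher, 187 lower) without vehicle replicate 1, 1022 (770 and 252) without vehicle replicate 2 and 1010 (758 and 252) without vehicle replicate 3. It moved them to 1552 (923 and 629) without imiquimod replicate 1 and 1260 (834 and 426) without imiquimod replicate 3. With no filter on low values 508 genes were lower. Log2 changes are given ± SE on the log2(FPKM + 0.1) scale, which understates the change of low genes.

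Interferon-stimulated genes rose together. Of 50 measured, 48 were higher and none was lower, with a median log2 change of 2.74 (camera adjusted p = 1.43e-33, adjusted p = 0.311 with an estimated correlation). Isg15 rose by 4.08 ± 0.32 (limma adjusted p = 0.00106) and Cxcl10, a chemokine for T and NK cells, by 4.18 ± 0.19, from 1.47 to 29 FPKM. Ifit2 (3.68 ± 0.21), Dhx58 (2.86 ± 0.20) and Herc6 (2.95 ± 0.23) were also higher. Irf7, a transcription factor of the interferon loop, stood at 3.58, 20.8 and 8.63 FPKM in the vehicle mice and at 234, 170 and 193 FPKM in the imiquimod mice (4.49 ± 0.56, limma adjusted p = 0.00439). The members that did not pass were Slfn5 (0.45 ± 0.22) and Tgtp1 (1.46 ± 0.63), the latter with an adjusted p of 0.0182 without imiquimod replicate 2. All 20 measured genes of MHC class I presentation were higher, with a median of 2.59 (camera adjusted p = 3.38e-23, adjusted p = 0.311 with an estimated correlation). They included H2-K1 (3.67 ± 0.17), H2-Q4 (4.19 ± 0.20), H2-Q6 (4.46 ± 0.21) and Psmb8, a subunit of the immunoproteasome (3.53 ± 0.18). Outside the lists, H2-Q5 (4.07 ± 0.15) and H2-M3 (2.32 ± 0.08) had the smallest adjusted p of the named genes, 1.87e-04 each. Class I heavy chain genes are close copies of each other, so how shared reads were counted bears on each single value. Of 6 measured class II presentation genes, 1 was higher, the peptide-loading gene H2-DMb1 (0.86 ± 0.12). That list did not pass, and its median was -0.17 although camera's direction was up (camera adjusted p = 0.624, adjusted p = 0.882 with an estimated correlation). The counts adjusted over the list alone were 48, 20 and 1 higher, as over all genes.

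**Figure D1:**
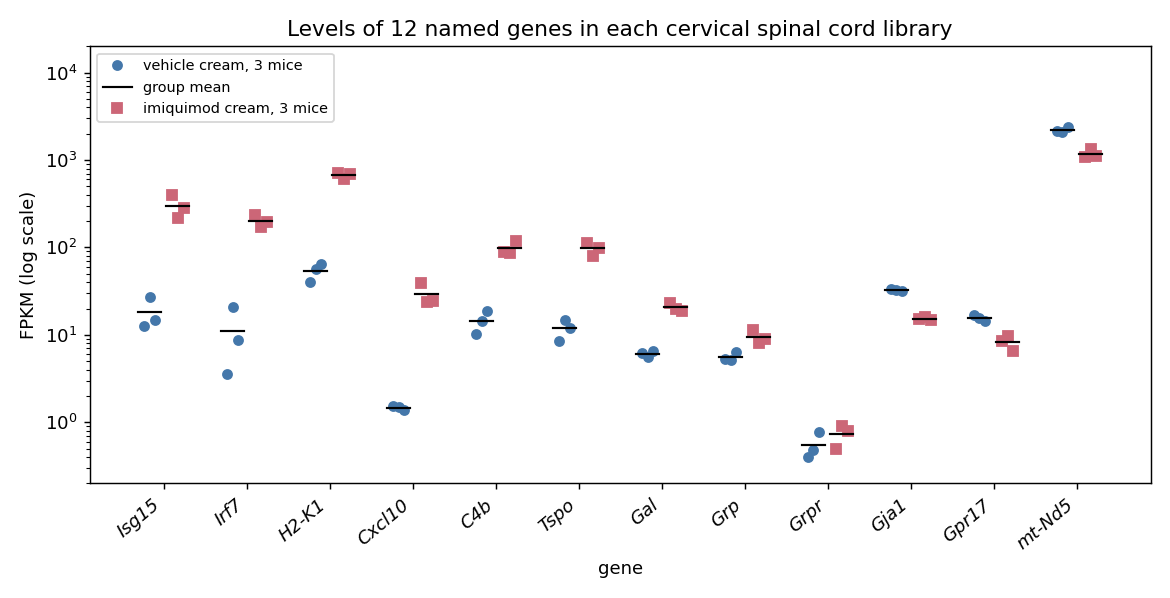
FPKM (log scale) of 12 named genes in each of the 6 cervical spinal cord libraries, with circles for the 3 vehicle mice, squares for the 3 imiquimod mice and black bars for the group means. The 3 imiquimod libraries lie above the 3 vehicle libraries for Isg15, Irf7, H2-K1, Cxcl10, C4b, Tspo, Gal and Grp, and below them for Gja1, Gpr17 and mt-Nd5, while Grpr overlaps.

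Of 36 cytokines and chemokines 22 were measured, of which 13 were higher and 2 lower (camera adjusted p = 1.75e-08, adjusted p = 0.311 with an estimated correlation). Members near 0 in vehicle cords entered only if higher in imiquimod cords. With no filter on low values the list passed too (camera adjusted p = 7.81e-12). Cxcl13, a B cell chemokine, had 1 recovered fragment over the 3 vehicle libraries and 908 over the 3 imiquimod libraries. At equal depth this is a ratio of 747, with a 95% exact interval of 134 to 29524 that covers counting error only. Ccl5 went from 1.24 ± 0.663 to 81.5 ± 25.3 FPKM (6.04 ± 0.46, limma adjusted p = 0.00106). Tgfb1 rose by 1.43 ± 0.12, and Cxcl9 and Ccl12 were higher as well. The lower members were Il33 (fell by 0.54 ± 0.11) and Cxcl12. Neither call held without vehicle replicate 1, vehicle replicate 3 or imiquimod replicate 1, nor that of Il33 without vehicle replicate 2 and that of Cxcl12 without imiquimod replicate 2 (adjusted p from 0.0506 to 0.093). Of 18 complement genes, 12 were higher and none was lower (camera adjusted p = 8.37e-08, adjusted p = 0.311 with an estimated correlation). Among them were C4b (14.4 ± 4.21 against 97.5 ± 16.9 FPKM), C3ar1 (2.90 ± 0.26), C1qa (1.42 ± 0.13) and C1ra (3.71 ± 0.35). In the Toll-like receptor and NF-kB pathway, 14 of 28 genes were higher and none was lower (camera adjusted p = 8.41e-07, adjusted p = 0.311 with an estimated correlation). They included Tlr7, the receptor of imiquimod (1.61 ± 0.24, 0.976 against 3.2 FPKM), Irf5 (1.62 ± 0.18) and Tlr3 (0.72 ± 0.11). Counts adjusted over the list alone were 15 higher and 2 lower for cytokines, 14 higher and 1 lower for complement and 17 higher and 1 lower for the Toll-like receptor list, where leaving out 1 library gave 8 to 15 higher.

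Genes of systemic inflammation and the STAT3 response were higher for 14 of 34 measured members, and for 23 adjusted over the list alone (camera adjusted p = 1.79e-10, adjusted p = 0.368 with an estimated correlation). Leaving out 1 library gave 7 to 26 higher. Examples were Timp1 (4.12 ± 0.32), Ch25h (3.33 ± 0.39), Ccl2 (3.58 ± 0.47) and Bcl3 (1.53 ± 0.21), and Stat3 itself rose by 0.47 ± 0.07 (limma adjusted p = 0.00678). Lcn2, an acute-phase protein that binds siderophores, was 1.46 ± 1.33 against 11 ± 8.8 FPKM and did not pass (2.80 ± 0.81, limma adjusted p = 0.063). Vehicle replicate 2 stood at 2.98 FPKM and imiquimod replicate 2 at 2.97 FPKM. That vehicle library also had the highest vehicle mean log2 of interferon-stimulated genes (2.28 against 1.15 and 1.59) and of neutrophil markers (2.22 against 0.676 and 1.17). Lcn2 passed without imiquimod replicate 2 (0.0229), with 1 CPM in 3 libraries (0.046) and with voom and quality weights (0.0393). In the IL-23 and IL-17 axis, 11 of 28 members were measured and 3 were higher (camera adjusted p = 0.0147, adjusted p = 0.368 with an estimated correlation). Its members near 0 in vehicle cords entered only if higher in imiquimod cords. With a minimum FPKM of 1 that list no longer passed (0.0785). The 3 were Il17ra, the A chain of the IL-17 receptor (1.88 ± 0.149 against 4.16 ± 0.49 FPKM, log2 change 1.10 ± 0.12), Il12b (2.56 ± 0.51) and Il12rb1 (1.34 ± 0.28). The call of Il12b ended without any one library except imiquimod replicate 2 (adjusted p from 0.0514 to 0.0897). That of Il12rb1 ended without vehicle replicate 1, vehicle replicate 3, imiquimod replicate 1 or imiquimod replicate 3 (0.0661 to 0.0873) and with no filter on low values (0.0531). Adjusted over the list alone, 6 members were higher and 1 lower, and leaving out 1 library gave 1 to 6 higher.

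Activated microglia genes were higher for 29 of 36 members, and for 30 adjusted over the list alone (camera adjusted p = 1.23e-18, adjusted p = 0.311 with an estimated correlation). Examples were Irf8 (1.82 ± 0.09), the lysosomal protease gene Ctsz (1.48 ± 0.08), Clec7a (2.49 ± 0.18) and Tspo, a mitochondrial outer membrane protein used to image glia, at 11.8 ± 3.14 against 97.7 ± 17 FPKM. Trem2, of the same list, did not pass (0.23 ± 0.11). Homeostatic microglia genes went both ways, 4 of 17 higher and 1 lower, and the list did not pass (camera adjusted p = 0.191, adjusted p = 0.746 with an estimated correlation). Tmem119 (1.14 ± 0.10), Olfml3 (1.03 ± 0.12) and Aif1, which encodes Iba1 (2.05 ± 0.21, 4.43 against 18.8 FPKM), were higher, and Fcrls fell by 0.70 ± 0.10. P2ry12 had a log2 change of -0.75 ± 0.21 and did not pass (limma adjusted p = 0.0591), but did in 5 alternatives, namely without imiquimod replicate 2, with 1 CPM in 3 libraries, with voom without and with weights and without length and GC trends (0.0362 to 0.0447). Of this list, 7 higher and 5 lower were counted adjusted over the list alone, and 3 higher and 4 lower over all genes without imiquimod replicate 2. Over all 6 libraries left out in turn, the counts ran from 3 to 6 higher and 1 to 4 lower. Reactive astrocyte genes were higher for 21 of 36 members, and for 29 adjusted over the list alone (camera adjusted p = 2.31e-17, adjusted p = 0.311 with an estimated correlation). Of the 21, 12 also stood on another list, such as Cxcl10, Psmb8 and the MHC class I gene H2-D1 (3.17 ± 0.16). Serpina3n (2.51 ± 0.18) was among the 21 as well, whereas Gfap was 573 ± 30.0 against 675 ± 51.6 FPKM and did not pass (0.23 ± 0.09, limma adjusted p = 0.151).

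Of 18 T and NK cell markers 9 were measured, of which 7 were higher and none was lower (camera adjusted p = 3.31e-06, adjusted p = 0.311 with an estimated correlation). Markers near 0 in vehicle cords entered only if higher in imiquimod cords, so the absence of lower ones says little. With no filter on low values the list passed as well (camera adjusted p = 9.21e-10). Gzmb (4.51 ± 0.54), Gzma (4.44 ± 0.69) and Nkg7 (2.85 ± 0.45) encode proteins of cytotoxic granules. Trbc1, a T cell receptor constant gene, had 3 recovered fragments over the vehicle libraries and 67 over the imiquimod libraries, a ratio of 18.4 (95% exact interval 6.02 to 91.3, counting error only). The median log2 change of the list was 2.52, and 2.85 with low-count members at their bound. Of 10 monocyte markers, 5 were higher (camera adjusted p = 2.61e-04, adjusted p = 0.368 with an estimated correlation), among them Ms4a4c (4.05 ± 0.45), Ccr2 (3.02 ± 0.43) and Ly6c2 (3.99 ± 0.65). The numbers adjusted over the list alone were 8 higher and 0 lower for T and NK cells and 7 higher and 0 lower for monocytes, and leaving out 1 library gave 4 to 7 and 3 to 7 higher. Of 9 neutrophil markers, Csf3r was higher and Mmp9 lower, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.624, adjusted p = 0.894 with an estimated correlation). The call of Csf3r ended without vehicle replicate 2, imiquimod replicate 1 or imiquimod replicate 3 (0.0519 to 0.0562), and that of Mmp9 without any one library except imiquimod replicate 2 (0.0938 to 0.136). S100a8, on the neutrophil list and the IL-17 list, was 12.1 ± 8.19 against 8.42 ± 1.62 FPKM (limma adjusted p = 0.635). Hemoglobin transcripts, a sign of residual blood, took 0.0197 ± 0.0140% of fragments in vehicle and 0.00671 ± 0.00460% in imiquimod mice (SD, n = 3 each, two-sided exact permutation p = 0.2). Red blood cell genes had a median of -1.48. None of 8 passed singly, and 5 were lower adjusted over the list alone (camera adjusted p = 0.00706, adjusted p = 0.368 with an estimated correlation).

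Of 51 measured itch and pain neuropeptides and receptors of the dorsal horn, 13 were higher and 2 lower (camera adjusted p = 2.28e-04, adjusted p = 0.311 with an estimated correlation). Adjusted over the list alone, 17 higher and 2 lower were counted. Gal rose by 1.73 ± 0.10 (limma adjusted p = 4.69e-04), the dynorphin precursor Pdyn by 1.23 ± 0.08, the neurokinin B precursor Tac2 by 0.93 ± 0.09 and Npr1, a natriuretic peptide receptor, by 1.44 ± 0.12. The precursors of corticotropin-releasing hormone (Crh, 1.53 ± 0.15), substance P (Tac1, 0.99 ± 0.12), enkephalin (Penk, 0.79 ± 0.09) and nociceptin (Pnoc, 0.83 ± 0.13) were higher too. Grp, the gastrin-releasing peptide of itch circuits, was 5.57 ± 0.699 against 9.42 ± 1.63 FPKM (0.74 ± 0.14, limma adjusted p = 0.0184). Its call ended without vehicle replicate 1 (0.0766) or vehicle replicate 2 (0.0688). The receptor gene Grpr was 0.551 ± 0.194 against 0.733 ± 0.209 FPKM and did not pass (0.36 ± 0.32, limma adjusted p = 0.481). The lower members were the receptor genes Ntrk2 (fell by 0.57 ± 0.08) and Ntsr2 (fell by 0.60 ± 0.11), the latter not without vehicle replicate 1 (0.066) or vehicle replicate 2 (0.06).

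Of 31 glutamate receptor and transporter genes, 4 were lower and none was higher (camera adjusted p = 7.84e-04, adjusted p = 0.39 with an estimated correlation). Grin2c fell by 1.02 ± 0.12 and the glial glutamate transporter Slc1a2 by 0.70 ± 0.10. The others, Gria1 and Gria4, lost their calls without any one library, except Gria4 without imiquimod replicate 2 (0.0518 to 0.129). Of 25 GABA and glycine signalling genes, 7 were lower and 1 higher (camera adjusted p = 1.94e-04, adjusted p = 0.368 with an estimated correlation). Slc12a2, which brings chloride into cells, fell by 0.60 ± 0.08, and Gad2, which makes GABA, rose by 0.41 ± 0.06. Of 9 cholinergic and motor neuron markers, 5 were lower (camera adjusted p = 1.53e-04, adjusted p = 0.368 with an estimated correlation). They were Chodl (-1.15 ± 0.26), Prph (-0.88 ± 0.21), Chat (-0.62 ± 0.15), Mmp9 and Ret. All 5 calls ended without any one vehicle library or imiquimod replicate 1, and those of Chat, Mmp9 and Ret also without imiquimod replicate 3 (adjusted p from 0.0703 to 0.148). With no filter on low values all 5 ended as well (0.0618 to 0.0907). Of 18 pan-neuronal markers, Elavl3 and Rbfox3 were lower and Gad2 higher (camera adjusted p = 0.0228, adjusted p = 0.494 with an estimated correlation), and the list did not pass with the length and GC trend removed (0.0894). The calls of Elavl3 and Rbfox3 ended without any one vehicle library, and that of Elavl3 without imiquimod replicate 3 (0.0528 to 0.0909). With p adjusted over the list alone, the counts were 0 higher and 8 lower for glutamate, 1 higher and 8 lower for GABA and glycine, 0 higher and 7 lower for motor neurons and 1 higher and 7 lower for neurons. Leaving out 1 library left 2 to 8, 1 to 10, 0 to 7 and 0 to 6 lower genes on these 4 lists.

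Among all lower genes, Gja1 had the smallest p (-1.10 ± 0.06, limma adjusted p = 3.43e-04). Next came Myoc (-2.39 ± 0.18), Nrep (-0.78 ± 0.06), AI464131 (-0.91 ± 0.07), Smyd1 (-1.80 ± 0.16), the thyroid hormone activating deiodinase Dio2 (-0.78 ± 0.07) and the zinc transporter Slc39a12 (-1.12 ± 0.10). Nadk2, Apln, Itm2a, Mturn and Tmprss5 completed the 12 named by that rule. Among 14 astrocyte markers, 5 were lower and 1 higher (camera adjusted p = 0.0147, adjusted p = 0.311 with an estimated correlation). The bicarbonate transporter Slc4a4 fell by 0.93 ± 0.11, as did Gja1 and Slc1a2 by the amounts above, and Aldh1l1 rose by 0.76 ± 0.08. Of 12 markers of oligodendrocyte precursors and new oligodendrocytes, 6 were lower and none was higher (camera adjusted p = 9.18e-04, adjusted p = 0.311 with an estimated correlation). Gpr17 led them, at 15.7 ± 1.24 against 8.23 ± 1.61 FPKM (-0.94 ± 0.15). Of 15 mature oligodendrocyte markers, 5 were lower and 1 higher (camera adjusted p = 0.00343, adjusted p = 0.532 with an estimated correlation), among them the lower Ugt8a (-0.87 ± 0.15). Its call ended without vehicle replicate 1 (0.0531), and that of the higher gene, Trf (0.73 ± 0.16), without any one library except imiquimod replicate 3 (0.0506 to 0.08). Of 23 cholesterol synthesis genes, 7 were lower and none was higher (camera adjusted p = 2.05e-05, adjusted p = 0.368 with an estimated correlation), with Sc5d (-0.48 ± 0.07) at the smallest p. Adjusted over the list alone, 3 higher and 7 lower were counted for astrocytes, 0 higher and 6 lower for precursors, 2 higher and 7 lower for oligodendrocytes and 0 higher and 14 lower for cholesterol synthesis. The lower genes on these lists numbered 3 to 7, 1 to 6, 0 to 5 and 2 to 10 when 1 library was left out.

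Mitochondrially encoded transcripts took 4.91 ± 0.316% of fragments in vehicle and 3.52 ± 0.366% in imiquimod mice (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). Of 13 mitochondrially encoded mRNAs, 5 were lower and none was higher, and 11 were lower adjusted over the list alone (camera adjusted p = 6.24e-06, adjusted p = 0.368 with an estimated correlation). With 1 library left out, 1 to 6 were lower. Their median log2 change was -0.80. The complex I subunit gene mt-Nd5 fell by 0.90 ± 0.13 (limma adjusted p = 0.00693). The calls of mt-Cytb, mt-Nd4 and mt-Nd2 ended without any one vehicle library, and that of mt-Nd2 also without imiquimod replicate 1 or 2 (0.0519 to 0.154). With no filter on low values none of these 4 passed (0.0787 to 0.4). Nuclear-encoded respiratory chain genes had a median of -0.09, and none of 42 passed singly, over all genes or adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.757 with an estimated correlation). That list no longer passed without vehicle replicate 3 (0.0756), imiquimod replicate 2 (0.0586) or imiquimod replicate 3 (0.845).

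**Figure D2:**
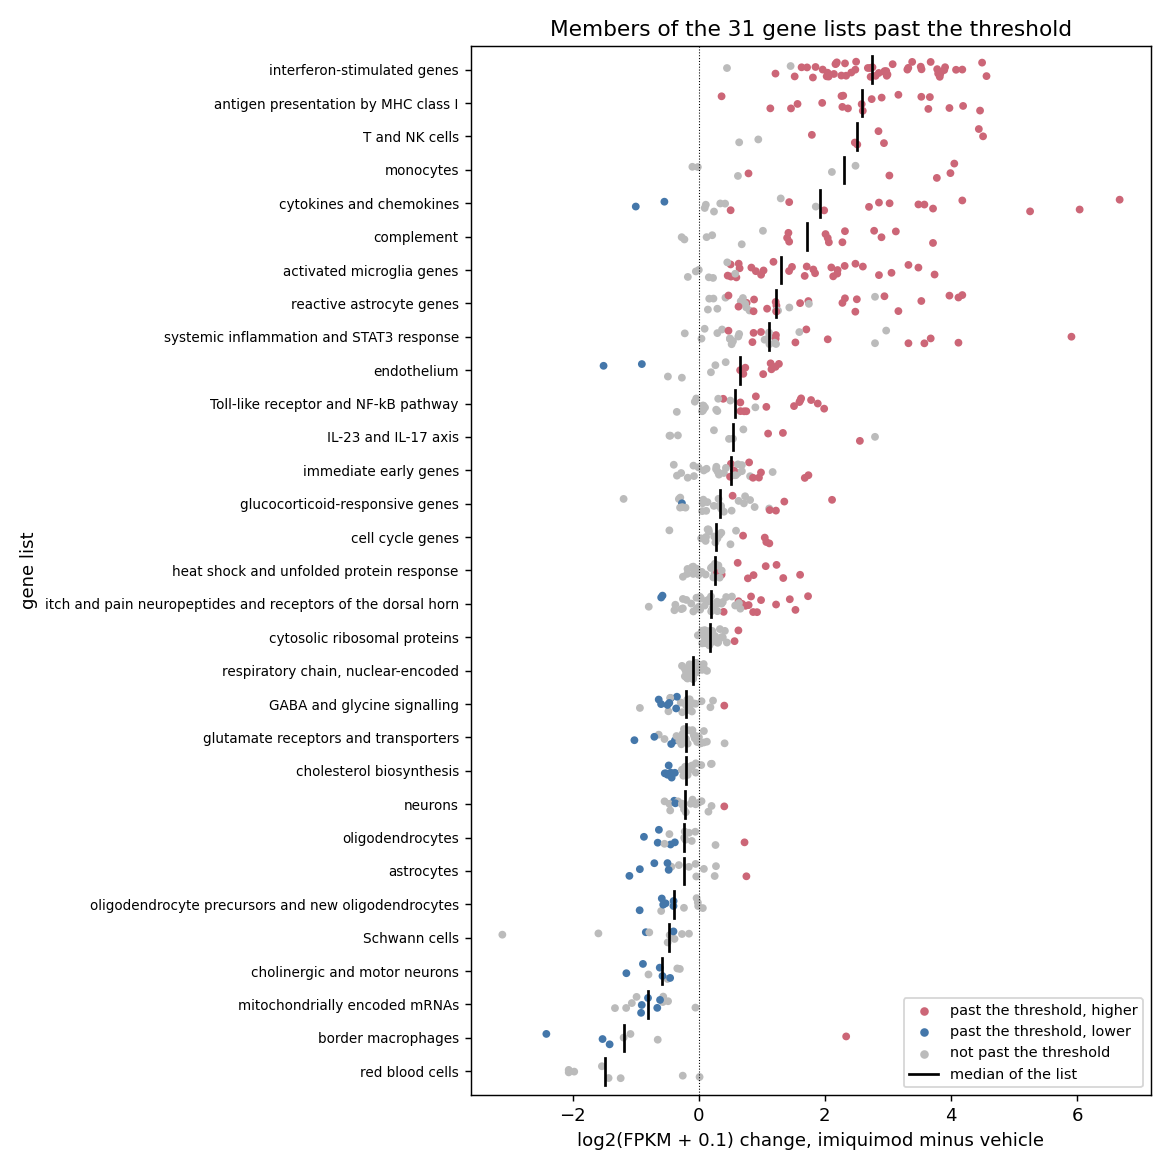
Log2(FPKM + 0.1) change, imiquimod minus vehicle, of each measured member of the 31 gene lists past the threshold, with lists on the vertical axis; points are genes, red where higher, blue where lower and grey where not past the threshold, and black bars are list medians. Interferon-stimulated genes (median 2.74) and MHC class I genes (median 2.59) lie at the top, and mitochondrially encoded mRNAs (median -0.80) near the bottom.

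Markers of the meninges differed within the imiquimod group. Ogn, a meningeal fibroblast gene, was 0.558 FPKM in imiquimod replicate 2, against 5.76 and 13.8 FPKM in the other imiquimod mice and 7.38 to 10.8 FPKM in the vehicle mice. Of 10 Schwann cell markers, Fbln7 and Sox10 were lower and none was higher (camera adjusted p = 0.00241, adjusted p = 0.311 with an estimated correlation), and without imiquimod replicate 2 the list and both genes still passed (list adjusted p = 0.014). Both calls ended without vehicle replicate 1, vehicle replicate 2 or imiquimod replicate 3, and that of Fbln7 without imiquimod replicate 1 (0.0562 to 0.121). Sox10 also stood on the list of oligodendrocyte precursors and new oligodendrocytes, so it is not particular to Schwann cells. Of 7 border macrophage markers, Cd163 (-1.41 ± 0.31), Mrc1 (-1.53 ± 0.39) and Pf4 (-2.42 ± 0.57) were lower and Ms4a7 (2.34 ± 0.47) was higher (camera adjusted p = 0.041, adjusted p = 0.642 with an estimated correlation). The list no longer passed without imiquimod replicate 2 (0.184), imiquimod replicate 1 (0.082), vehicle replicate 2 (0.0772) or vehicle replicate 3 (0.0714). All 4 gene calls ended without any one vehicle library or imiquimod replicate 1, those of Mrc1 and Pf4 without imiquimod replicate 2 and that of Ms4a7 without imiquimod replicate 3 (0.0546 to 0.149). Of 14 meningeal fibroblast markers, Thbs2 was higher, though not without any one vehicle library (0.0534 to 0.0918), and the list did not pass (camera adjusted p = 0.683, adjusted p = 0.979 with an estimated correlation). Without imiquimod replicate 3 that list passed in the lower direction (0.0167). Adjusted over the list alone, 0 higher and 3 lower were counted for Schwann cells, 1 higher and 3 lower for border macrophages and 1 higher and 0 lower for fibroblasts.

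Of the 44 lists with at least 3 measured genes, 31 passed, 18 in the higher and 13 in the lower direction. None passed with an estimated correlation between genes (lowest adjusted p = 0.311). MHC class I presentation, with all 20 genes higher, had that same value, so with 6 libraries this test had little power. The test with a preset correlation rests on genes more than on mice, so its small p-values can overstate the certainty. On the mm10 assembly (GRCm38), Isg15 (ENSMUSG00000035692) lies on chromosome 4, 156199424 to 156200818, reverse strand, H2-K1 (ENSMUSG00000061232) on chromosome 17, 33996017 to 34000347, reverse strand, and Cxcl10 (ENSMUSG00000034855) on chromosome 5, 92346638 to 92348889, reverse strand. Tlr7 (ENSMUSG00000044583) lies on chromosome X, 167304929 to 167330558, reverse strand, Gal (ENSMUSG00000024907) on chromosome 19, 3409915 to 3414544, reverse strand, and Gja1 (ENSMUSG00000050953) on chromosome 10, 56377330 to 56402513, forward strand. All 6 are annotated as protein-coding, and their values are over annotated exons. Exons of Cxcl10, Irf7, Stat3, Tspo, Ctsz, Irf5, Gpr17 and mt-Nd5 overlap exons of Art3, Phrf1, Stat5a, Mcat, Nelfcd, Tnpo3, Lims2 and mt-Nd6 on the other strand. Those of Atf5, Ddit3, Plin4, Egfl7 and Cebpd overlap exons of Nup62, Mars, Hdgfl2, Agpat2 and Spidr in the same way. Further named genes, such as Psmb8, H2-Q4, Npr1 and Slc1a2, also overlap other annotated genes there, and these examples are not all. Whether fragments were counted by strand is not given in the sources used here, so those values are uncertain to that extent.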

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

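Of the 128 named genes that passed, 88 kept direction and call under each of the 20 alternatives in which they were tested except the log2 threshold, and 67 under that as well. No named gene chosen by the rule changed direction. Of the 37 genes chosen after their values were seen, 17 stayed on their side of the threshold, apart from the alternatives that change the threshold. Leaving out vehicle replicate 1 ended 37 of the calls, vehicle replicate 2 31, vehicle replicate 3 29, imiquimod replicate 1 20, imiquimod replicate 2 6 and imiquimod replicate 3 16. These fits have fewer samples. Depth limits low genes: 3 fragments in a 2 kb gene are an FPKM of 0.0639 to 0.0863. Thinning to equal depth and removing length and GC trends were chosen after seeing the data; they shared 2132 and 1995 of the 2326 calls. The planned edgeR fits (with trimmed-mean, median-of-ratios or total scaling), the DESeq2 fit and the prior counts of 2 and 0.5 were not run, although fragments could be recovered; limma-voom on them gave 2585 genes (1503 higher, 1082 lower), of which 2154 were among the 2326. Other pseudocounts stood in for the prior counts.

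The count of 2326 genes (1444 higher, 882 lower) was 3674 at an adjusted p under 0.1 (2086 higher, 1588 lower) and 693 with a log2 change of at least 1 (623 higher, 70 lower), both by construction. With no filter on low values, 508 genes were lower, and with length and GC trends removed, 1480; the cause was not tested. Leaving out 1 library gave 847 to 2986 genes, 660 to 1690 higher and 187 to 1296 lower, and 29 to 31 lists. The lowest of the gene counts came without vehicle replicate 1 and the highest without imiquimod replicate 2. With the replicate number as a replicate block, 1330 genes passed (894 higher, 436 lower), of which 1280 were among the 2326, and 31 lists passed. Same-numbered libraries did not visibly deviate together (correlations 0.0186, -0.0970 and -0.0331, against -0.102 to 0.134 for libraries of different number). With 3 libraries per group this cannot exclude that the numbers pair the mice. Under the remaining alternatives the counts stayed within 1.5 times.

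Of the 31 lists, 0 passed with an estimated correlation and 20 with fry, which lost 11 and gained hypoxia and glycolysis (0.0493). Apart from these tests, 24 lists passed under every alternative. Besides those given with the lists above, glucocorticoid-responsive genes were lost without vehicle replicate 1 (0.0564) or imiquimod replicate 3 (0.179), ribosomal proteins without imiquimod replicate 1 (0.103), border macrophages with a minimum FPKM of 1 (0.114) or without length and GC trends (0.102), and red blood cells without mitochondrial and hemoglobin genes (0.0952). Circadian clock genes passed without imiquimod replicate 3 (0.0322).

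Of the 13 lists that did not pass, 8 changed camera's direction in at least 1 alternative, in no case past the threshold (lowest adjusted p = 0.1402); the cause was not tested. For sensory ganglion neurons the adjusted p was 0.8707 with library totals and with no filter, 0.9623 with 1 CPM in 3 libraries, 0.9059 with voom and weights, 0.9682 with the block, 0.9275 without mitochondrial and hemoglobin genes, 0.9391 without length and GC trends, and 0.8012 to 0.9538 leaving out 1 library. For ependymal cells it was 0.8704 with library totals, 0.7378 with no filter, 0.7977 with 1 CPM, 0.9247 with voom, 0.9275 without mitochondrial and hemoglobin genes and 0.7781 to 0.984 leaving out 1 library. For B and plasma cells it was 0.9082 with no filter, 0.6687 with 1 CPM, 0.9762 with voom, 0.9682 with the block, 0.9809 without length and GC trends and 0.5922 to 0.9549 leaving out 1 library. For skeletal muscle it was 0.6536 with 1 CPM, 0.899 thinned and 0.5949 to 0.9548 leaving out 1 library. Leaving out 1 library also turned MHC class II presentation (0.05763 to 0.883 over the libraries), pericytes (0.1674 to 0.8603), meningeal fibroblasts (0.01673 to 0.9619, turned without imiquimod replicate 2) and neutrophils (0.1354 to 0.8346). The log2 change of S100a8, which did not pass, ran from -0.6682 to 0.1843 and turned without vehicle replicate 2.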

Other observations

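Endothelial genes rose in part. Of 15 measured, 8 were higher and 2 lower, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.311 with an estimated correlation). The tight junction gene Cldn5 (1.14 ± 0.09), the adhesion molecule Pecam1 (1.27 ± 0.09) and Egfl7 (1.22 ± 0.18) were higher, while the anion transporter Slco1a4 of the blood-brain barrier fell by 0.90 ± 0.12. The other lower gene, Slco1c1, lost its call without any one library except imiquimod replicate 2 (0.0677 to 0.13). Of 28 heat shock and unfolded protein response genes, 10 were higher and none was lower (camera adjusted p = 8.75e-05, adjusted p = 0.368 with an estimated correlation), with 13 higher adjusted over the list alone. Ddit3 (1.34 ± 0.09), Atf5 (1.23 ± 0.12), Chac1 (0.87 ± 0.12) and Hspb1 (1.61 ± 0.16) were examples, of which the first 3 act downstream of Atf4. Of 18 cell cycle genes, 4 were higher, also adjusted over the list alone (camera adjusted p = 0.00361, adjusted p = 0.368 with an estimated correlation): Mcm3 (1.05 ± 0.13), Mcm6 (1.07 ± 0.13), Mcm5 and Tpx2. Mcm3 and Mcm6 help to license DNA replication. The calls of Mcm5 and Tpx2 ended without imiquimod replicate 1 or 3, and that of Mcm5 also without imiquimod replicate 2, vehicle replicate 1 or vehicle replicate 3 (0.0587 to 0.108). Of 32 immediate early genes, 9 were higher (camera adjusted p = 1.94e-04, adjusted p = 0.494 with an estimated correlation), with 13 higher and 1 lower adjusted over the list alone. Maff (1.68 ± 0.23), Jund (0.56 ± 0.08) and the phosphatase Dusp6 (0.51 ± 0.07) were among them. Of 30 glucocorticoid-responsive genes, 5 were higher and 1 lower (camera adjusted p = 0.0147, adjusted p = 0.685 with an estimated correlation), with 11 higher and 3 lower adjusted over the list alone. Plin4 (2.11 ± 0.36) and Cdkn1a (1.13 ± 0.19) kept their calls whichever library was left out, while those of Mt1, Cebpd, Sgk1 and the lower Mfsd2a each ended without 2 or more single libraries (0.0559 to 0.108). That list was lost without vehicle replicate 1 (0.0564) or imiquimod replicate 3 (0.179). Leaving out 1 library gave 6 to 12 higher for heat shock, 2 to 4 for cell cycle, 4 to 14 for immediate early and 3 to 9 for glucocorticoid-responsive genes.

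Other lists held few changed genes. Of 50 cytosolic ribosomal protein genes, Rps20 (0.57 ± 0.12) was among 2 that were higher, and no gene passed adjusted over the list alone (camera adjusted p = 1.94e-04, adjusted p = 0.685 with an estimated correlation); its call ended without any one vehicle library (0.083 to 0.091). Of 22 hypoxia and glycolysis genes, Hk2 (1.13 ± 0.15), Adm (0.94 ± 0.13), Ldha (0.56 ± 0.08) and Hk1 were higher and Ndrg1 fell by 0.45 ± 0.06; the call of Hk1 ended without any one vehicle library or imiquimod replicate 3 (0.0665 to 0.122). That list did not pass (camera adjusted p = 0.644, adjusted p = 0.734 with an estimated correlation), and its median of 0.05 was -0.04 with length and GC trends removed. Of 7 ependymal genes, Rarres2 (1.73 ± 0.23) was higher and Ccdc153 lower, the latter not without vehicle replicate 1 or 3 (0.0504 to 0.0581), and the list did not pass (camera adjusted p = 0.978, adjusted p = 0.979 with an estimated correlation). Of 3 B and plasma cell genes, Ighm fell by 0.44 ± 0.06 (camera adjusted p = 0.959, adjusted p = 0.979 with an estimated correlation), although the list median was 0.42. Pericytes and smooth muscle had Higd1b and Kcnj8 higher and Rgs5 lower of 10 (camera adjusted p = 0.608, adjusted p = 0.746 with an estimated correlation), sensory ganglion neurons 1 gene higher and Prph lower of 7 (camera adjusted p = 0.978, adjusted p = 0.979 with an estimated correlation), circadian clock genes Nr1d1 lower of 20 (camera adjusted p = 0.178, adjusted p = 0.685 with an estimated correlation) and keratinocytes Krt10 lower of 4 (camera adjusted p = 0.498, adjusted p = 0.685 with an estimated correlation). The calls of the 6 genes named each ended without at least 4 of the single libraries (0.0579 to 0.129). None of 4 skeletal muscle genes (camera adjusted p = 0.959, adjusted p = 0.979 with an estimated correlation) or of 4 sex-linked genes (camera adjusted p = 0.193, adjusted p = 0.408 with an estimated correlation) passed. From hypoxia and glycolysis on, the counts adjusted over the list alone were the same, except for B and plasma cells (1 higher and 1 lower).

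The tests of dilution, of fewer mitochondria-rich cells, of residual blood, of entry of NK cells and of less meningeal tissue were chosen or reworded after the result was seen, and the others before. Mitochondrially encoded mRNAs were lower by a median of 0.80. Low recovery of AT-rich transcripts would lower nuclear genes of like GC content, but the median of 1497 such genes was -0.08216 (quartiles -0.26 and 0.07). Dilution by induced genes would lower most genes in library totals, but the median of all genes was 0.04265. Fewer mitochondria-rich cells would lower nuclear-encoded respiratory chain genes, whose median was -0.09261 (quartiles -0.14 and -0.03). With length and GC trends removed it was -0.1994, against -0.7633 for the mitochondrially encoded mRNAs. A change in mitochondrial transcripts per cell may remain as a hypothesis, without a test of its own here, and RNA quality before library preparation was not measured in these files.

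Of 9 T and NK cell markers 7 were higher, and of 10 monocyte markers 5. More residual blood in the imiquimod cords would raise hemoglobin genes, whose median log2 change was -1.798. For entry of NK cells, 13 further NK cell genes had been fixed before their values were seen. A filter on either group's mean keeps those that rose, so all 13 were taken with no filter on low values. Their median log2 change was 1.849, a figure that depends on the pseudocount, with 12 changes above 0 and 1 below, and 7 passed. The one below was S1pr5 (-0.26 ± 0.10), which was at 33.9 FPKM in vehicle cords and did not pass. Of 8 T cell receptor complex genes taken in the same way all changes were above 0 and none passed (median 0.67). Here and among the NK cell genes, a gene at or near 0 in vehicle cords can hardly show a fall, so the signs say little. None of the 8 was high enough to enter the main test, so the lack of calls says little. Trbc1, a T cell receptor gene outside that set, did pass (limma adjusted p = 0.00739). NK cells, T cells or both in the imiquimod cords or their meninges could give these values. This stays a hypothesis, since resident cells could also induce such genes.

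Of the border macrophage markers, Cd163, Mrc1 and Pf4 were lower. Less meningeal tissue would lower meningeal fibroblast markers alike. In imiquimod replicates 1 and 3 the median change of 14 fibroblast markers was 0.5971 (quartiles -0.03 and 0.81). Their mean log2 was 2.35 in replicate 1 and 3.48 in replicate 3, against 2.19, 2.87 and 2.46 in the vehicle libraries. Cd163, Mrc1 and Pf4 kept a median of -1.199 there, though 1 of the 3 passed without replicate 2. Their place under every vehicle library followed from their choice as markers that fell. Over all 7 measured markers, the mean log2 was -0.644 in replicate 1 and 0.323 in replicate 3, against -0.003, 0.447 and 0.324 in vehicle. The list as a whole thus did not fall in replicate 3. Fibroblast means lay within or above the vehicle range in replicates 1 and 3, which less meningeal tissue alone would not give. Ogn, however, was low in replicate 1. Schwann cell markers went the other way. Their mean log2 was 2.85 in replicate 1 and 3.27 in replicate 3, against 3.40, 3.34 and 3.55 in the vehicle libraries. Marker levels could also change with treatment, so less meningeal tissue is not excluded there. In imiquimod replicate 2, the mean of border macrophage markers relative to that of fibroblast markers was -2.28, against -2.19, -2.42 and -2.14 in the vehicle libraries (difference from their mean -0.02637), so less meningeal tissue may account for the fall in that library. For loss of border macrophages, 5 further genes had a median of -0.05955 and went both ways, Mgl2 at -2.29 ± 0.46 and Stab1 at 0.81 ± 0.23 at the ends, so loss of cells stays open too.

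The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2326 genes (1444 higher, 882 lower), and each of the others gave 0. Every other split has vehicle and imiquimod libraries on both sides. The treatment difference then adds to the spread within each side, so gene counts near 0 were likely beforehand. The real split gave 31 lists, and the others gave 7 to 25. The mixed splits still hold part of the treatment difference, so their list counts do not show what no difference would give. The splits therefore cannot decide whether the counts arose by chance. Imiquimod that reached the blood could also raise interferon-stimulated genes without the dermatitis, and this design cannot separate the drug from the skin disease.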
